A study of Homo sapiens with 6 samples.

How the data were processed

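RNA sequencing was carried out on 6 libraries of Flip-In-293 cells, a derivative of the human embryonic kidney line HEK293. The cells carried a lentiviral short hairpin RNA against CPSF2, against RBFOX2, or a non-silencing hairpin. Each of the 3 groups has 2 libraries, which the series' design text describes as biological replicates. Per the labels' protocols, total RNA was extracted from the cells with a silica column kit and libraries were made with a TruSeq kit for an Illumina HiSeq instrument. CASAVA 1.8.2, TopHat2 2.0.9, Bowtie2 2.1.0 and the human build hg19 are named per the submitters' processing notes, and the design text names DEXSeq for exon usage. The annotation release, the counting strand setting and the version of the counting program are not given in the sources used here.

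The authors deposited 1 table of raw read counts per library, with 588114 exon bins under 54630 gene identifiers. A bin is a stretch of exon between neighbouring annotated exon borders, so an exon with alternative ends spans several bins, and a read counts in each bin it overlaps. Gene totals are therefore sums of bin counts and not numbers of reads. In the deposited count tables, 2161 identifiers join several overlapping genes. A further 4 lines of each table name no gene and stayed out of library sizes and tests. Reads outside exons made up 5.05% and 4.37% of all counts in the CPSF2 knockdown libraries, 4.21% and 4.61% in the RBFOX2 knockdown libraries, and 3.41% and 3.29% in the non-silencing libraries. Ambiguous reads made up between 2.55% and 2.70%, and the lines for low quality and unaligned reads held 0.

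Gene names came from the identifier table given with the reference, with GENCODE v29 for strand, gene type, transcript length and GC content. Symbols were found for 91.1% of the 52469 single identifiers. GENCODE v29 is on another build than the deposited tables, so no coordinates were taken from it, and bins are named by their number in the tables. The last (3′) bin of a gene is its highest numbered bin on the plus strand and its lowest on the minus strand. End bins are the first and last bin of a gene in the tables, and all others are called internal.

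Differential expression was tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, with all 6 libraries in 1 model so that the groups shared 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values and calls were made at 0.05. Bin usage was tested with edgeR's diffSpliceDGE on bins with a mean count of at least 10 in genes with at least 2 such bins, which gives the log2 change of a bin relative to its gene. Usage in percent is the bin's share of its gene's total count. Internal and end bins were compared with a two-sided Fisher's exact test on 1 bin per gene, the called bin with the smallest p. Genes are not independent replicates, so p-values of Fisher's exact tests do not measure the spread between libraries. DEXSeq was not used here, and its model was fitted in DESeq2 1.42.0 as an alternative, with only the 2 groups compared. It gave no adjusted p for 17951, 53843 and 41884 bins in the CPSF2, RBFOX2 and direct comparisons. Because both knockdowns share the non-silencing libraries, unchanged groups were simulated against those libraries, 10 times for genes and 3 times for bins.

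The 30 gene lists held 515 entries, of which 475 matched an identifier, 56 were left out because the identifier joins them with other genes, and 419 were used. The lists cover the cleavage and polyadenylation specificity factor (CPSF) complex, the cleavage stimulation factor with symplekin, other 3′ end factors, histone 3′ end factors, Integrator subunits, histone genes, the RBFOX family, genes with RBFOX-regulated exons, SR proteins, hnRNP proteins, tissue splicing regulators, core spliceosome proteins, nonsense-mediated decay factors, cytosolic ribosomal proteins and mitochondrially encoded genes. They also cover interferon genes, p53 targets, mitotic (G2/M) genes, DNA replication genes, the integrated stress response, endoplasmic reticulum chaperones, cholesterol synthesis, immediate early genes, heat shock proteins, mesenchymal and epithelial genes, and markers of blood, neural, fibroblast or endothelial, and HeLa or liver cells. The 29 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. Adjusted p-values of lists are over the 29 lists of a comparison.

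Named genes followed a rule. CPSF2 and RBFOX2 are always named. Each expression comparison adds the 8 largest increases and 8 largest decreases with a mean CPM (counts scaled to library size, per 1e+06 bin counts) of at least 5 among called single genes with a symbol, plus up to 4 called members per list with the smallest p. Each bin comparison adds the 8 smallest p in each direction at a mean count of at least 50 and an absolute relative log2 change of at least 1, 1 bin per gene, plus the smallest-p bin of genes with RBFOX-regulated exons. The overlap adds the 8 genes with the smallest of their larger p. Members of the CPSF, cleavage stimulation factor and RBFOX lists may be named in every case. Not every gene or bin that the rule admits is reported here, and 1 such gene also stays out of the counts of named genes. The groups, tests, lists, naming rule and alternative settings were fixed before the data were examined.

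The alternative settings fixed then were DESeq2's Wald test and its size factors, other filters on low counts, the highest bin of a gene in place of the sum, 2 groups per model, a replicate block, merged identifiers left out, other definitions of end bins, 2-fold calls only, an estimated correlation for lists, and leaving out each library in turn. Chosen after the data were seen were a model with each library's trend over bin position taken out, restricted to genes of known strand, a crossed pairing, a removal of the trend over transcript length and GC content from the list tests, and a list of genes regulated by hypoxia-inducible factors.

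The procedures were tested on simulated data for the CPSF2 knockdown against the non-silencing control. Over 21434 genes, edgeR called 81.6% of 98 genes changed 2-fold and 64.3% of 98 changed 1.5-fold, with 10 unchanged genes called. Over 292283 bins of 14401 genes, it called 95.9% of 97 bins changed 4-fold and 75.5% of 98 changed 2-fold, with 61 unchanged bins called. The DEXSeq model called 87.6% and 57.1% of them, with 22 unchanged bins called. With a planted graded trend along transcripts, 28967 unchanged bins of 292407 were called, and 61 once the trend was taken out. Counts of called bins are therefore given with and without the trend. The planted trend was estimated from these libraries with the same position classes as its removal, so the removal was built in. It does not show that a trend differing between genes would be removed. All simulated counts were drawn independently, with spreads taken from the fits and equal in all groups. For bins, the spread depended on the count level only. Real bins of a gene can share reads, so the numbers of unchanged genes and bins called do not give error rates in these libraries.

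Bin counts summed to between 153920898 and 189303181 per library. Between replicates, the chi-square per gene was 30.4 in the CPSF2 knockdown, 6.68 in the RBFOX2 knockdown and 9.34 in the control. Reads counted in several bins raise these values by themselves, by an amount not estimated. How far replicates differed beyond sampling noise is therefore not known from them. With 2 libraries per group, a gene's SD rests on 1 difference, and tests borrow the spread across genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.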

Results

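The deposited tables gave exon bin counts for 6 libraries of Flip-In-293 cells, 2 with a hairpin against CPSF2, 2 with a hairpin against RBFOX2 and 2 with a non-silencing hairpin. CPSF2 encodes a subunit of the complex that recognises the polyadenylation signal and cleaves pre-mRNA at its 3′ end. RBFOX2 encodes an RNA-binding protein that regulates alternative exons. The study asked whether 3′ end formation factors act on the usage of internal exons. Bin counts summed to 153920898 and 189303181 in the CPSF2 knockdown, 182899210 and 188818716 in the RBFOX2 knockdown, and 171927491 and 175984387 in the control libraries. Values below are means ± SD over 2 libraries per group (n = 2), and adjusted p-values of genes and bins are Benjamini-Hochberg values from edgeR's quasi-likelihood tests.

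Both hairpins lowered their targets. CPSF2 (ENSG00000165934) stood at 37.0 ± 0.684 CPM in its knockdown and 77.5 ± 6.06 CPM in the control, which leaves 47.7% and is a log2 change of -1.07 ± 0.06 (SE; adjusted p = 6.5e-08). RBFOX2 (ENSG00000100320) stood at 46.8 ± 0.235 CPM in its knockdown and 81.8 ± 4.0 CPM in the control, which leaves 57.3% (log2 change -0.80, adjusted p = 2.8e-07). RBFOX2 was 1.53-fold higher in the CPSF2 knockdown, at 125 ± 0.256 CPM (log2 change 0.61, adjusted p = 5.0e-07). CPSF2 stood at 70.8 ± 1.55 CPM in the RBFOX2 knockdown, a log2 change of -0.13 that missed the threshold (adjusted p = 0.064). This change was -0.14 without either CPSF2 knockdown library, and -0.11 and -0.16 without RBFOX2 knockdown library 1 or 2. It depended most on the controls, at -0.06 and -0.22 without control library 1 or 2. Among other 3′ end factors, the CPSF endonuclease gene CPSF3 fell by 0.32 on the log2 scale in the CPSF2 knockdown and by 0.31 in the RBFOX2 knockdown. Neither call was kept with the highest bin in place of the gene total, where the changes were -0.06 and -0.13. WDR33, which contacts the polyadenylation signal, had a log2 change of -0.01 in the CPSF2 knockdown. The scaffold gene SYMPK fell by 0.32 in the CPSF2 knockdown but was 0.33 higher when only its highest bin was counted. The RBFOX family member RBFOX3 fell by 0.44 in the CPSF2 knockdown (adjusted p = 2.8e-04) and had a log2 change of -0.14 in the RBFOX2 knockdown.

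**Figure D1:**
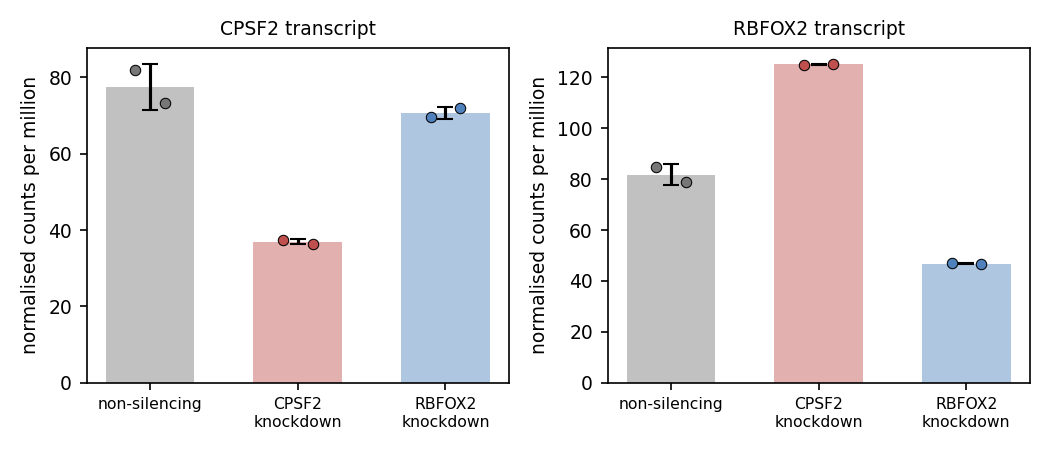
CPM (y axis, from 0) of CPSF2 and RBFOX2 in the 3 groups. Bars are means, error bars are SD (n = 2) and points are single libraries; CPSF2 falls from 77.5 to 37.0 in its knockdown, while RBFOX2 falls from 81.8 to 46.8 in its own knockdown and stands at 125 in the CPSF2 knockdown.

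The first comparison asked what the CPSF2 knockdown changed in gene expression. STC1, which encodes the secreted glycoprotein stanniocalcin 1, rose by 2.56 ± 0.07 (SE) on the log2 scale, from 6.51 ± 0.0209 to 38.5 ± 1.55 CPM. The collagen lysyl hydroxylase gene PLOD2 rose from 87.5 ± 4.47 to 336 ± 19.2 CPM (log2 change 1.94), and the circadian repressor gene BHLHE41 from 8.07 ± 0.346 to 32.3 ± 3.33 CPM (2.00). ZDBF2, ZNF292 and PPFIA4 rose by 2.06, 1.93 and 1.85. Among called single genes with a symbol and a mean CPM of at least 5, the largest decrease was that of CGA. This gene of the common alpha subunit of the glycoprotein hormones fell by 3.03 from 9.96 ± 0.12 to 1.21 ± 0.37 CPM (adjusted p = 3.2e-08). FGF13, an intracellular member of the fibroblast growth factor family, fell by 2.05, and SPR, the last enzyme of tetrahydrobiopterin synthesis, fell by 1.91. PPIL1, a cyclophilin of the spliceosome, fell by 1.77, GEMIN2, which takes part in assembly of spliceosomal ribonucleoproteins, by 1.60, and the phospholipid-binding protein gene ANXA1 by 1.44. RPL36AL fell by 2.13, a value that is uncertain because reads can be shared with near-identical copies of this ribosomal protein gene. Of 22099 genes tested, 5739 were higher and 6081 lower, with 1030 and 614 of them changed at least 2-fold.

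In the CPSF2 knockdown, genes with RBFOX-regulated exons rose as a group. Of 22 tested members, 18 rose and 1 fell, the same numbers as adjusted over the list alone, with a median log2 change of 0.46 (camera adjusted p = 2.5e-11, and adjusted p = 0.355 with an estimated correlation). Besides PLOD2, the adducin gene ADD3 rose by 0.98 and ENAH, a regulator of actin filaments, by 0.99. Log2 changes rose with transcript length and fell with GC content across 19509 genes (Spearman correlations across genes 0.169 and -0.292; genes are not independent replicates), and the list's median was 0.24 once this trend was taken out (adjusted p = 5.4e-06). All 10 mitochondrially encoded genes fell, also adjusted over the list alone, with a median of -0.92 (camera adjusted p = 1.0e-10, and adjusted p = 0.355 with an estimated correlation). The respiratory complex I gene MT-ND2 fell by 1.31 and MT-ND3 of the same complex by 1.10, both uncertain because reads can be shared with nuclear copies. Of 26 cytosolic ribosomal protein genes, 24 fell and 25 adjusted over the list alone (median -0.51, camera adjusted p = 1.8e-13, and adjusted p = 0.385 with an estimated correlation). RPS19 fell by 0.93 and RPLP1 by 0.77. Reads of such genes can be shared with pseudogenes, and the length and GC check is void for this list because only 17 of 26 members had a length.

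The integrated stress response list fell in the CPSF2 knockdown, with 14 of 17 members lower and 2 higher in both adjustments, all genes and adjusted over the list alone (median -0.54, camera adjusted p = 1.3e-07, and adjusted p = 0.355 with an estimated correlation). ASNS, asparagine synthetase, fell by 1.00 from 385 ± 13.2 to 193 ± 9.04 CPM, the amino acid transporter subunit gene SLC3A2 fell by 0.89 and the pseudokinase gene TRIB3 by 0.88, whereas DDIT4, an inhibitor of mTOR signalling, rose by 1.10. Of 23 DNA replication genes 18 fell and 1 rose, the same adjusted over the list alone (median -0.29, camera adjusted p = 1.0e-04, and adjusted p = 0.355 with an estimated correlation). The licensing factor gene CDT1 fell by 0.75 and the cyclin gene CCNE1 by 0.57. Of 20 core spliceosome genes 17 fell and 1 rose, or 17 and 2 adjusted over the list alone (median -0.27, camera adjusted p = 7.9e-04, and adjusted p = 0.638 with an estimated correlation). The Sm protein genes SNRPF and SNRPE fell by 0.81 and 0.54, while SF3B1 of the U2 particle rose by 0.54. Among 20 p53 targets 12 fell and 4 rose, or 13 and 4 adjusted over the list alone (median -0.34, camera adjusted p = 0.011, and adjusted p = 0.355 with an estimated correlation). The cell cycle inhibitor gene CDKN1A fell by 0.60 and the cytokine gene GDF15 by 0.75. Of 11 heat shock genes 7 fell, the same adjusted over the list alone (median -0.30, camera adjusted p = 0.012, and adjusted p = 0.593 with an estimated correlation). The small heat shock protein gene HSPB1 fell by 0.53, and HSPA1B, which can share reads with its near-identical neighbour, by 0.73. Of 3 tested CPSF subunits 2 fell, the hairpin's own target CPSF2 and CPSF3, the same adjusted over the list alone (camera adjusted p = 0.041, and adjusted p = 0.385 with an estimated correlation). Because the hairpin's target is 1 of the 3 members, this call does not show a fall of the complex's other genes. With an estimated correlation, camera called 0 of the 29 lists, 3 had an unadjusted p under 0.05, and fry called 15.

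The next comparison asked which exon bins changed in use within their genes after CPSF2 knockdown. The last bins of several genes were used less. The last bin of CTDSPL2, a phosphatase gene, fell from 11 ± 0.719% to 3.16 ± 0.232% of the gene's counts (relative log2 change -1.81, adjusted p = 7.6e-37). The last bin of KMT2A, a histone methyltransferase gene, fell from 20.4 ± 0.945% to 7.94 ± 0.267%, that of PRRC2C from 14.9 ± 0.429% to 5.69 ± 0.169%, and that of the homeobox gene HMBOX1 from 44.5 ± 1.36% to 13.7 ± 1.84%. Among bins far from the 3′ end, INTS3 bin 11 rose from 1.11 ± 0.0272% to 3.58 ± 0.019% (relative log2 change 1.69, adjusted p = 1.3e-37). INTS3 encodes a subunit of the Integrator and SOSS complexes. ANAPC5 bin 35, in a subunit gene of the anaphase-promoting complex, rose from 1.26 ± 0.00553% to 3.33 ± 0.151%, and FAT1 bin 50, in an atypical cadherin gene, from 0.984 ± 0.0531% to 4.72 ± 0.151%. Bin 87 of the mucin gene MUC16 rose from 5.17 ± 1.65% to 26.1 ± 1.53%. The FAT1 bin is number 50 of 52 and the MUC16 bin number 87 of 89, both near the 5′ end of minus strand genes. With each library's trend over bin position taken out, their relative log2 changes were 1.97 and 2.01. That removal covers only a trend shared by all genes. Of 308659 bins in 15067 genes, 51149 were used more and 28421 less, with 9045 and 2592 at 2-fold or more.

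Usage in the CPSF2 knockdown moved with position along the gene. The last bin had a median relative log2 change of -0.31 and bins 20 or more before it 0.22. The last 3 bins held a median of 23.4% and 23.2% of a gene's counts in the 2 CPSF2 knockdown libraries, 25.8% and 26.0% in the RBFOX2 knockdown and 28.9% in both control libraries, over 9245 genes. Of called bins at the 3′ end 93.8% were lower, against 12.1% at the 5′ end. With 1 bin per gene, 51.8% of internal bins and 84.1% of end bins were lower (two-sided Fisher's exact test, p = 6.6e-175), and with the position trend taken out 45.4% and 59.7%. The test counts genes as independent, although a position trend is shared across the genes of a library. Its p-value does not measure the spread between libraries, and end bins pool the 5′ and 3′ ends. Internal bins can include parts of first and last exons, so they do not stand for internal exons. Over all called bins 33.4% of internal and 76.0% of end bins were lower, and at 2-fold 28.2% and 58.1%. With each library's position trend taken out, 39466 bins of 294976 were called, against 75299 of the same bins before. Of all calls 40.9% were still called in the same direction, and of the 2-fold calls 76.0%, while the number at 2-fold or more went from 10882 to 6723. The DEXSeq model called 39973. Leaving out control library 1 gave 47633 called bins and leaving out control library 2 gave 40942.

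**Figure D2:**
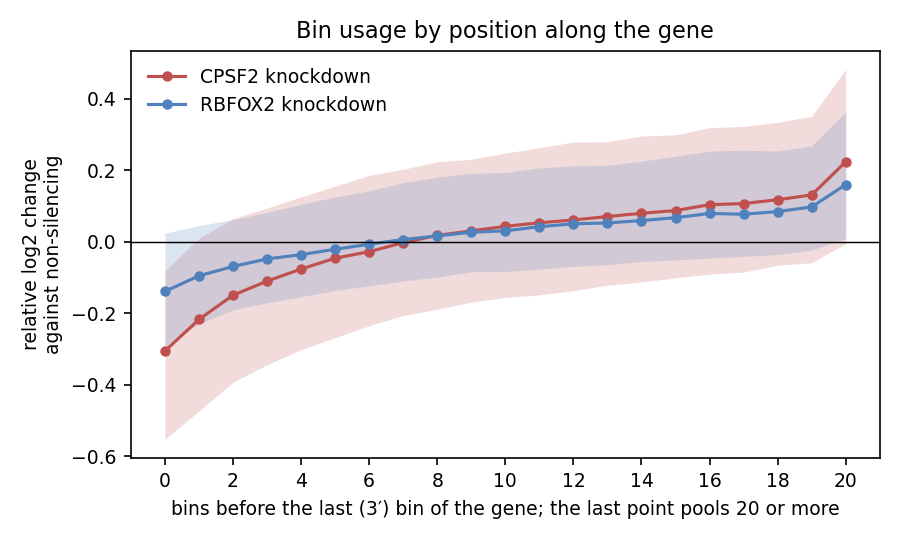
Relative log2 change of bin usage against the non-silencing control (y axis) by number of bins before the last (3′) bin of the gene (x axis) in both knockdowns. Points are medians over bins and shaded bands span the quartiles; in the CPSF2 knockdown the median goes from -0.31 at the last bin to 0.22 at 20 or more bins before it, and in the RBFOX2 knockdown from -0.14 to 0.16.

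The third comparison asked what the RBFOX2 knockdown changed in gene expression. EMILIN2, an extracellular matrix glycoprotein gene, rose by 2.49 ± 0.10 (SE) on the log2 scale, from 1.96 ± 0.128 to 11 ± 0.286 CPM. GADD45B, a stress sensor gene, rose from 21.6 ± 0.745 to 63.4 ± 0.786 CPM (log2 change 1.55), SNAI1, a repressor of epithelial genes, by 1.44 and ARC, an activity-regulated gene, by 1.32. PLA2G4C, a phospholipase gene, rose by 1.96. DNAH17, an axonemal dynein gene, rose by 2.06, a value that is uncertain because an antisense gene overlaps it and the counting strand is not given in the sources used here. NKIRAS2, an inhibitor of NF-kappaB signalling, fell by 1.64 from 93.7 ± 2.69 to 30.0 ± 0.523 CPM, and the arrestin family gene ARRDC4 by 1.56 from 102 ± 1.5 to 34.5 ± 0.26 CPM. ABCG1, a cholesterol exporter gene, and BST2, which encodes the antiviral protein tetherin, each fell by 1.48. TMSB4X fell by 2.16, a value that is uncertain because reads can be shared with near-identical copies. Of 22099 genes tested, 5187 were higher and 5724 lower, with 1183 and 356 changed at least 2-fold.

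Cholesterol synthesis genes fell in the RBFOX2 knockdown, with 13 of 16 lower and 2 higher, the same adjusted over the list alone (median -0.40, camera adjusted p = 2.4e-06, and adjusted p = 0.694 with an estimated correlation). INSIG1, which retains the sterol sensor in the endoplasmic reticulum, fell by 0.70, the isomerase gene IDI1 by 0.67 and HMGCS1, an early enzyme of the pathway, by 0.52. Of 16 immediate early genes 9 rose and 3 fell, the same adjusted over the list alone (median 0.25, camera adjusted p = 2.3e-04, and adjusted p = 0.751 with an estimated correlation). The transcription factor genes FOSB, FOS and EGR1 rose by 2.15, 1.08 and 1.01, FOSB from 1.87 ± 0.0711 to 8.30 ± 0.163 CPM. All 26 cytosolic ribosomal protein genes fell, also adjusted over the list alone (median -0.49, camera adjusted p = 2.1e-15, and adjusted p = 0.751 with an estimated correlation), among them RPL34 by 0.55 and RPS6 by 0.51. Between the knockdowns 4 of the 26 were higher and 9 lower, or 3 and 7 adjusted over the list alone (median -0.06, camera adjusted p = 0.507). Against the same 2 control libraries, the share of counts in the last 3 bins was lower and reads outside exons more frequent in both knockdowns. All 10 mitochondrially encoded genes fell, also adjusted over the list alone (median -0.39, camera adjusted p = 2.2e-04, and adjusted p = 0.751 with an estimated correlation). In the integrated stress response list 11 of 17 fell and 4 rose, the same adjusted over the list alone (median -0.32, camera adjusted p = 0.0075, and adjusted p = 0.744 with an estimated correlation). PCK2, a mitochondrial enzyme of gluconeogenesis, fell by 0.86 and DDIT4 by 0.94, while SLC3A2 rose by 0.60. Genes with RBFOX-regulated exons were split, with 10 of 22 higher and 4 lower, also adjusted over the list alone (median 0.06, camera adjusted p = 0.128). Without control library 1 this list passed (adjusted p = 0.0229), as did histone genes (0.0402). Log2 changes again fell with GC content across genes (Spearman correlation -0.195), and with the length and GC trend taken out the called lists other than the ribosomal one, for which that check is void, stayed called. With an estimated correlation, camera called 0 of the 29 lists, 1 had an unadjusted p under 0.05, and fry called 10.

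Bin usage in the RBFOX2 knockdown changed inside several genes with RBFOX-regulated exons. CLSTN1 bin 12, in the gene of the membrane protein calsyntenin 1, fell from 1.64 ± 0.0501% to 0.487 ± 0.0735% of the gene's counts (relative log2 change -1.75, adjusted p = 1.1e-21). FN1 bin 58, in the fibronectin gene, fell from 0.765 ± 0.103% to 0.240 ± 0.0168%, and GOLIM4 bin 11, in a Golgi membrane protein gene, from 2.37 ± 0.0533% to 0.734 ± 0.021%. PICALM bin 18, in a clathrin assembly gene, fell from 0.970 ± 0.00978% to 0.361 ± 0.105%. Outside that list, EPB41L2 bin 29, in a membrane skeleton gene, fell from 1.72 ± 0.0408% to 0.560 ± 0.00892%, and MARK3 bin 56, in a microtubule-associated kinase gene, from 0.715 ± 0.0456% to 0.146 ± 0.014%. Higher use was seen at NKIRAS2 bin 14, from 0.371 ± 0.0227% to 2.15 ± 0.165%, COA1 bin 5, from 2.56 ± 0.229% to 7.16 ± 0.12%, and bin 33 of the splicing factor gene TRA2B, from 0.634 ± 0.0043% to 1.55 ± 0.062%. At least 1 bin was called in 19 of 22 genes with RBFOX-regulated exons, or 86.4%, against 42.1% of all 15067 genes (two-sided Fisher's exact test, p = 3.0e-05). An excess was also seen in the CPSF2 knockdown (22 of 22, against 67.6%, Fisher's exact test p = 3.0e-04) and in the direct comparison (21 of 22, against 56.3%, Fisher's exact test p = 1.0e-04). The 22 genes hold 791 of the 308659 tested bins, more per gene than all genes do, and the test was not matched for this. Of these 791 bins, 57 were higher and 42 lower in the RBFOX2 knockdown, and FGFR2 bin 29, in a growth factor receptor gene, was higher by 1.09.

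In the same 308659 bins, the RBFOX2 knockdown had 18222 bins used more and 6297 less, with 4021 and 479 at 2-fold or more. The last bin had a median relative log2 change of -0.14 and bins 20 or more before it 0.16. With 1 bin per gene, 28.1% of internal and 70.5% of end bins were lower (two-sided Fisher's exact test, p = 2.4e-150, with genes again counted as independent), and with the position trend taken out 24.9% and 46.2%. At 2-fold 12% and 25.4% were lower. Of called bins at the 3′ end 84.3% were lower, against 6.22% at the 5′ end. Bins called higher at 2-fold lay at a median level of 1.83% of their gene's strongest bin and bins called lower at 2-fold at 3.88%, against 20.3% for bins not called. In the CPSF2 knockdown these values were 3.54%, 7.05% and 19.5%. With the position trend taken out 11697 bins were called, against 22933 of the same bins before, and 43.3% of all calls and 72.2% of the 2-fold calls were still called in the same direction. The number at 2-fold or more went from 4199 to 2910. The DEXSeq model called 14711, against 39973 in the CPSF2 knockdown, and the model of 2 groups 46190, against 67457. How many fewer bins were called than in the CPSF2 knockdown therefore depends on the model. In the main model the CPSF2 knockdown libraries enter the spread used for the RBFOX2 comparison. The count of 24519 called bins became 46184 and 46274 without CPSF2 knockdown library 1 or 2, 8433 and 6158 without RBFOX2 knockdown library 1 or 2, and 8607 and 7025 without control library 1 or 2.

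**Figure D3:**
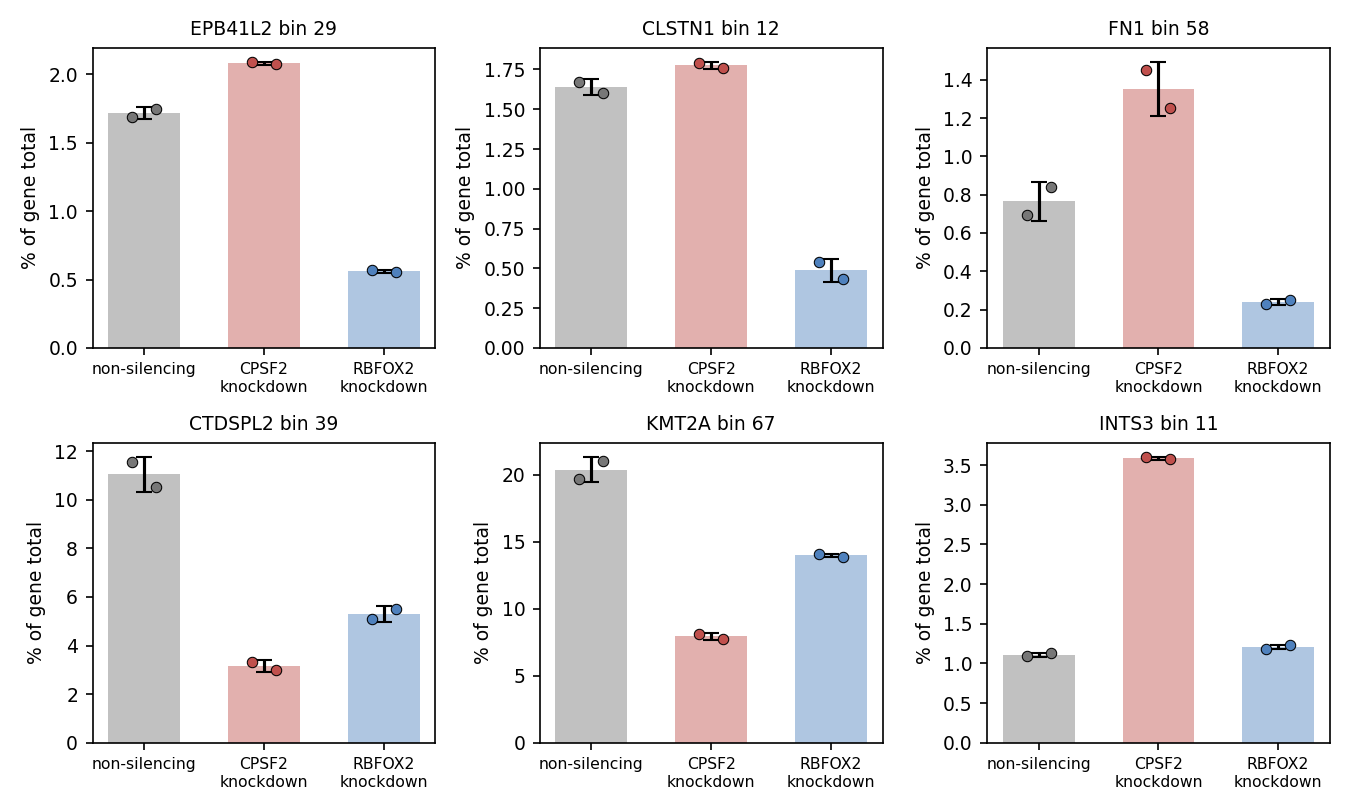
Usage of 6 exon bins as a percentage of their gene's counts (y axis, from 0) in the 3 groups. Bars are means, error bars are SD (n = 2) and points are single libraries; EPB41L2 bin 29, CLSTN1 bin 12 and FN1 bin 58 are lowest in the RBFOX2 knockdown, the last bins of CTDSPL2 and KMT2A are lowest in the CPSF2 knockdown, and INTS3 bin 11 is highest there.

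The CPSF2 and RBFOX2 knockdowns were compared with each other directly. STC1 was higher in the CPSF2 knockdown by 2.91 on the log2 scale, the neurite outgrowth gene NRN1 by 2.04, DDIT4 by 2.04, the pyruvate dehydrogenase kinase gene PDK1 by 1.95 and the extracellular protease gene ADAMTS1 by 1.97, from 133 ± 0.61 CPM in the RBFOX2 knockdown to 522 ± 12.7 CPM. ARC, GADD45B, SNAI1 and the kinase gene SGK1 were lower by log2 changes of -2.47, -2.42, -2.11 and -2.09. Of 16 immediate early genes 13 were lower and 1 higher, the same adjusted over the list alone (median -0.48, camera adjusted p = 2.0e-06, and adjusted p = 0.544 with an estimated correlation), among them FOSB at -2.60 and CCN2 at -2.05. Of 22 genes with RBFOX-regulated exons 17 were higher and 1 lower, the same adjusted over the list alone (median 0.28, camera adjusted p = 4.5e-06, and adjusted p = 0.544 with an estimated correlation), and of 16 cholesterol genes 10 were higher and 1 lower, the same adjusted over the list alone (median 0.21, camera adjusted p = 3.1e-04, and adjusted p = 0.477 with an estimated correlation). STARD4, a sterol carrier, was higher by 1.56 and INSIG1 by 1.00. DNA replication genes (15 of 23 lower and 2 higher, 16 and 2 adjusted over the list alone), mitochondrially encoded genes (6 of 10 lower, 7 adjusted over the list alone with 1 higher), p53 targets (13 of 20 lower and 5 higher, also adjusted over the list alone), the integrated stress response (11 of 17 lower and 3 higher, 11 and 4 adjusted over the list alone) and core spliceosome genes (13 of 20 lower and 2 higher, also adjusted over the list alone) were called lower, with camera adjusted p = 0.0051, 0.0051, 0.011, 0.012 and 0.026. With an estimated correlation their adjusted p = 0.477, 0.614, 0.477, 0.477 and 0.685 in the same order. With the length and GC trend taken out, the last 4 of these 5 lists missed the threshold (adjusted p = 0.0612, 0.0612, 0.0848 and 0.0612). The mitochondrial list also missed it without CPSF2 knockdown library 1 (0.0539), and the spliceosome list without CPSF2 knockdown library 1 (0.124), RBFOX2 knockdown library 1 (0.0623), control library 1 (0.0545) or control library 2 (0.0543). The heat shock list, at adjusted p = 0.0622, passed without CPSF2 knockdown library 2 (0.00379) or RBFOX2 knockdown library 2 (0.0261). With an estimated correlation, camera called 0 lists, 2 had an unadjusted p under 0.05, and fry called 20.

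In the direct comparison of bins, bins of FN1, EPB41L2 and CLSTN1 that fell in the RBFOX2 knockdown were used more in the CPSF2 knockdown than there. FN1 bin 58 held 1.35 ± 0.141% of the gene's counts in the CPSF2 knockdown and 0.240 ± 0.0168% in the RBFOX2 knockdown (relative log2 change 2.47, adjusted p = 1.1e-28). EPB41L2 bin 29 held 2.08 ± 0.0104% and 0.560 ± 0.00892%, and CLSTN1 bin 12 held 1.78 ± 0.0208% and 0.487 ± 0.0735%. Against the control, the CPSF2 knockdown had relative log2 changes of 0.82 at the FN1 bin (adjusted p = 2.2e-07), 0.28 at the EPB41L2 bin (adjusted p = 0.022) and 0.12 at the CLSTN1 bin (adjusted p = 0.46). ENAH bin 12 held 3.41 ± 0.241% in the CPSF2 knockdown and 1.17 ± 0.0817% in the RBFOX2 knockdown. FARP1 bin 69 and ZNF451 bin 25 were used less in the CPSF2 knockdown, at 3.33 ± 0.0585% against 9.26 ± 0.385% and 3.64 ± 0.838% against 13.1 ± 0.31%. Of genes tested, 6417 were higher and 6339 lower in the CPSF2 knockdown, and of bins 19352 and 22353. The DEXSeq model called 13300 bins, and the bin count of 41705 became 68852 without CPSF2 knockdown library 1, 13832 without RBFOX2 knockdown library 1 and 13841 without RBFOX2 knockdown library 2. With the position trend taken out 30182 bins were called, and 64.9% of all calls and 91.4% of the 2-fold calls were still called in the same direction.

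The last comparison asked how far the 2 knockdowns overlapped. Called in both in the same direction were the last bins of CTDSPL2, of ENAH and of the epigenetic silencing gene TASOR. ENAH's last bin fell from 4.05 ± 0.0316% to 1.11 ± 0.0658% in the CPSF2 knockdown and 1.82 ± 0.144% in the RBFOX2 knockdown, and TASOR's from 6.70 ± 0.0908% to 2.78 ± 0.388% and 2.92 ± 0.053%. FAT1 bin 49 rose from 1.58 ± 0.122% to 6.12 ± 0.267% and 3.68 ± 0.349%, and bin 72 of the spliceosome gene PRPF8 from 0.620 ± 0.0105% to 1.29 ± 0.174% and 1.08 ± 0.00032%. Both lie near the 5′ end of minus strand genes, of 52 and 78 bins. Bins of HNRNPA1, PGK1 and RPL37 were also called in both and are uncertain because reads can be shared with processed copies. Of 16632 bins called in both knockdowns, 16127 or 97.0% changed in the same direction, 11359 higher and 4768 lower, against 3020 and 580 for independent lists. With the position trend taken out 5668 of 6024 did. Of genes called in both, 5387 of 7111 or 75.8% changed in the same direction, 2407 higher and 2980 lower, against 1347 and 1575 for independent lists. The correlation of log2 changes across genes was 0.237 with covariance 0.0995, and unchanged groups simulated against the same controls gave 0.523 and 0.0288. For bins the values were 0.570 and 0.0898, with 0.529 and 0.0249 simulated. Of 479 bins used at least 2-fold less in the RBFOX2 knockdown, 142 were lower, 37 higher and 300 not called in the CPSF2 knockdown, where their median relative log2 change was -0.36. Of 4021 bins used at least 2-fold more, 1958 were higher, 32 lower and 2031 not called there (median 0.86). Both sets of bins were picked against the same control libraries, which by itself favours the same direction. How far it does so was not simulated for them. In the simulations of unchanged groups, means of 0.7 and 2.5 genes were called in the CPSF2 and RBFOX2 comparisons and 0.3 in both, with 0 bins. With so few calls, they cannot show how far the shared controls raise the overlap of calls. The numbers for independent lists do not allow for the shared controls either. The 16127 bins became 26603 and 29981 without CPSF2 knockdown library 1 or 2, 5393 and 3965 without RBFOX2 knockdown library 1 or 2, and 5536 and 4119 without control library 1 or 2.

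The remaining lists were not called in any of the 3 comparisons at the preset correlation. Numbers of members that rose and fell are given first for the CPSF2 and then for the RBFOX2 knockdown, each against the control. Other 3′ end factors had 6 up and 2 down of 8, then 4 and 1, with NUDT21, the small subunit of cleavage factor I, higher by 0.47 and 0.24. The cleavage stimulation factor with symplekin had 0 and 2 of 5, then 1 and 2. Histone 3′ end factors had 2 and 2 of 6, then 3 and 3, with the transcription coactivator gene NPAT higher by 0.94 and 0.50. Integrator subunits had 5 and 6 of 12, then 5 and 3, with INTS6 higher by 0.70 and 0.78, and histone genes had 8 and 1 of 21, then 7 and 4. SR proteins had 4 and 4 of 11, then 6 and 1, with SRSF10 higher by 0.53 and 0.49. The hnRNP proteins had 2 and 4 of 14 both times, and tissue splicing regulators 11 and 4 of 18, then 6 and 4, with RBM25 higher by 0.81 and 0.32 and QKI by 0.59 in the CPSF2 knockdown. With the length and GC trend taken out, SR proteins (median -0.23, adjusted p = 0.0493) and hnRNP proteins (median -0.25, adjusted p = 0.0328) were called lower in the CPSF2 knockdown. In the CPSF2 knockdown, tissue splicing regulators and immediate early genes (1 up and 7 down of 16) stood at adjusted p = 0.078 each and passed without CPSF2 knockdown library 2 (0.0475 each) or control library 1 (0.0317 each).

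Nonsense-mediated decay factors had 5 up and 3 down of 9 in the CPSF2 knockdown, then 3 and 0 in the RBFOX2 knockdown. Endoplasmic reticulum chaperones had 4 and 8 of 14, then 7 and 5, with the degradation factor gene SEL1L higher by 0.84 and 0.50. Interferon genes had 3 and 6 of 21, then 5 and 5. Mitotic (G2/M) genes had 5 and 7 of 19, then 5 and 5, with CDC20, an activator of the anaphase-promoting complex, lower by a log2 change of -0.60 in the CPSF2 knockdown. Mesenchymal genes had 5 and 6 of 16 both times, with ZEB1 higher by 1.03 and 0.64 and VIM, which encodes vimentin, at -0.60 and -0.54. Epithelial genes had 5 and 5 of 12, then 2 and 4, with the cadherin gene CDH1 higher by 0.53 in the CPSF2 knockdown. The median levels were 0.48 CPM for blood, 0.55 CPM for fibroblast or endothelial and 0.10 CPM for HeLa or liver markers, with 2 and 2 of 8, 0 and 0 of 8, and 0 and 2 of 7 up and down in the CPSF2 knockdown and 2 and 1, 2 and 0, and 4 and 0 in the RBFOX2 knockdown. Neural markers, at a median of 4.84 CPM, had 4 and 3 of 11, then 2 and 5, and the enolase gene ENO2 rose by 0.83 and fell by 0.72. Adjusted over the list alone, the numbers differed for the cleavage stimulation factor (0 and 1) and SR proteins (4 and 5) in the CPSF2 knockdown, and for other 3′ end factors (4 and 2), histone genes (8 and 5), tissue splicing regulators (7 and 4), epithelial genes (2 and 6), core spliceosome genes (4 and 9) and CPSF subunits (0 and 2) in the RBFOX2 knockdown. Cholesterol genes had 6 and 6 of 16 in the CPSF2 knockdown, and in the RBFOX2 knockdown DNA replication genes had 5 and 10 of 23, p53 targets 6 and 7 of 20, heat shock genes 2 and 3 of 11, core spliceosome genes 3 and 9 of 20, and CPSF subunits 0 and 1 of 3.

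**Figure D4:**
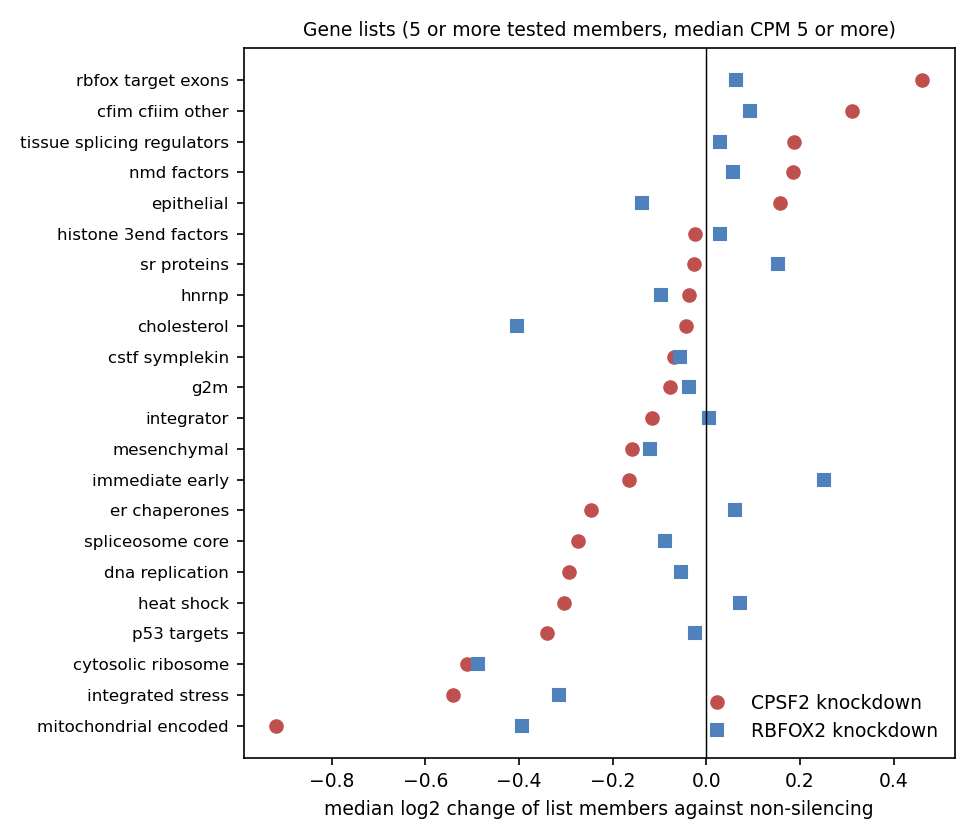
Median log2 change of list members against the non-silencing control (x axis) for lists with at least 5 tested members and a median CPM of at least 5 (y axis), without the genes of hypoxia-inducible factors, with circles for the CPSF2 and squares for the RBFOX2 knockdown. Mitochondrially encoded genes are lowest in the CPSF2 knockdown at -0.92 and genes with RBFOX-regulated exons highest at 0.46; cytosolic ribosomal protein genes are lowest in the RBFOX2 knockdown at -0.49.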

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

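The joint test of genomic DNA was written down before its result was seen, whereas the separate tests of the 2 knockdowns were chosen after it was seen. Reads that fell outside annotated exons, which no comparison used, were more frequent in both knockdowns than in the controls. Per 100 bin counts there were 5.08 ± 0.544 such reads in the CPSF2 knockdown and 4.74 ± 0.323 in the RBFOX2 knockdown, against 3.57 ± 0.0932 in the non-silencing libraries (n = 2 each), or 1.42 and 1.33 times the control level. The difference was not tested.

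Genomic DNA in the libraries would raise reads over 341 olfactory receptor genes, which are silent in most cells. Taken jointly, the lower of the 2 knockdowns stood at 1.03 times the control level on these genes, which argues against genomic DNA as the cause in both. The CPSF2 knockdown alone stood at 1.02 times, with an interval of 0.887 to 1.18 and libraries at 1.10 and 0.956 times. This also argues against it there, but does not exclude a small amount. Both intervals in this paragraph take bin counts as separate reads, although a read counts in each bin it overlaps, so they can be too narrow. The RBFOX2 knockdown stood at 1.67 times, with an interval of 1.48 to 1.89 that covers counting error only and libraries at 1.61 and 1.73 times. Genomic DNA in those libraries could produce this, but wider low-level transcription may give the same value and was not separated from it. Reading past weakened polyadenylation sites is a biological explanation given by the CPSF2 hairpin, and it was not tested because the tables hold no positions outside exons.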

How the results depend on the processing

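Of values of named genes under the alternatives, 4976 of 5081 kept direction and call, 97 lost the call and 8 reversed. Named genes and bins were picked for large changes or small p in these data, so their rates do not describe all calls. With the highest bin in place of the gene total, 7777 of 11820, 7122 of 10911 and 9304 of 12756 gene calls were kept in the same direction in the CPSF2, RBFOX2 and direct comparisons. For bins 1785 of 1838 kept direction and call and 53 lost the call. For lists 829 of 870 values stayed called or stayed not called, where lists not called could change direction. Of the others, 31 lost the call, 9 gained it in the same direction and 1 in the other direction. All reversals came with the highest bin in place of the gene total: SYMPK at 0.33, 0.17 and 0.16 in the CPSF2, RBFOX2 and direct comparisons, CSTF2T at 0.043, H4C16 at -0.12, TOP2A at -0.031 and -0.017, and HYOU1 at -0.058; the cause was not tested. Among settings with 2 libraries in every group, CPSF2 in the RBFOX2 knockdown passed the threshold with no filter (-0.15), the highest bin (-0.28), 2 groups in the model (-0.13) and the crossed block (-0.13). The cause was not tested. With an estimated correlation 0, 0 and 0 lists were called (unadjusted 3, 1 and 2), and with the length and GC trend taken out 11, 5 and 4 lists (the ribosomal list, where this check is void, in the first 2), SR and hnRNP proteins newly in the CPSF2 knockdown. The DEXSeq model called 39973, 14711 and 13300 bins, 2 groups in the model 46190 for RBFOX2, and with the position trend taken out 39466 and 11697 were called and 5668 shared. At 2-fold the overlap was 207 genes and 1692 bins, fewer by construction.

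Leaving out 1 library, which leaves a lone sample assumed to vary like the other groups, gave 9600 to 11622, 7907 to 12170 and 10248 to 12524 genes in the 3 comparisons and 40942 to 91877, 6158 to 46274 and 13832 to 68852 bins. CPSF2 ranged from -1.15 to -0.99, -0.22 to -0.056 and -0.95 to -0.91, and RBFOX2 from 0.56 to 0.66, -0.86 to -0.76 and 1.41 to 1.43. Lists called were 9 to 11, 5 to 7 and 6 to 9, the overlap 3767 to 6019 genes and 3965 to 29981 bins, and internal minus end bins -35.9 to -30.5 and -47.8 to -38.4 points. Libraries share only a replicate number, with correlations of -0.26, 0.04 and -0.26 between groups. A block on it gave 11486, 10413 and 12352 genes and 76535, 22634 and 38666 bins and changed no other count by over 1.5 times. With this block 2 of 365 named gene values and 1 of 115 named bin values lost the call. Pairing the RBFOX2 libraries crosswise gave 12178, 11343 and 13107 genes and 83759, 28234 and 45915 bins.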

Other observations

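The list of genes regulated by hypoxia-inducible factors was chosen after the largest changes were seen, and its 2 tests were set before the list was tested. The 4 tests of the 3′ end pattern were chosen after that pattern was seen.

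Several of the largest increases in the CPSF2 knockdown, such as STC1, PLOD2 and PPFIA4, are genes known to respond to hypoxia-inducible factors. In a list of 28 tested genes of this kind, from which 10 genes seen first were left out, 25 rose and 1 fell in the CPSF2 knockdown, with a median log2 change of 0.68 (camera p = 0.00957 with an estimated correlation). The p-values of this list are unadjusted, unlike those of the other lists. In the same camera test the integrated stress response list had an unadjusted p = 0.0131 and an adjusted p = 0.355. KDM3A, a histone demethylase gene, rose by 1.47, the mitophagy gene BNIP3L by 1.40, the glycolytic regulator gene PFKFB3 by 1.19 and NDRG1 by 1.16. In the RBFOX2 knockdown 3 rose and 19 fell (median -0.24, camera p = 0.122 with an estimated correlation), among them the glycolytic gene TPI1 by 1.16, while KDM3A rose by 1.00.

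The hypoxia pattern reached genes beyond those seen first, with the median of 0.68, so a hypoxia-type response may be present in the CPSF2 knockdown. Gene length and GC content do not account for it, because 85.5% of the median was kept once their trend was taken out. Oxygen, cell density and medium age per library are not given in the sources used here, so an effect of the knockdown and one of culture both stay open and untested.

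Bins near the 3′ end were used less in both knockdowns. A coverage difference shared by all genes may account for most called bins, since 40.9% of them stayed called in the CPSF2 knockdown with the trend taken out. Of the 2-fold calls 76.0% stayed called at any size, so the trend as removed does not account for all of them. It was removed as a median per library and class of bin position. Afterwards 45.4% of internal and 59.7% of end bins were lower, with 1 called bin per gene. A coverage difference that varies between genes would remain, so coverage stays open as a cause of the 2-fold calls too. The knockdown of CPSF2 alone is argued against by values seen before the test, since the last bin's median was -0.14 in the RBFOX2 knockdown and its last 3 bins held 25.8% and 26.0% of a gene's counts, against 28.9% in both controls. This argument rests on control libraries that both knockdowns share. The pattern was stronger in the CPSF2 knockdown. Against the RBFOX2 knockdown, its last bin had a median of -0.18, and 90.3% of called 3′ end bins were lower. With 1 bin per gene 58.2% of internal and 83.9% of end bins were lower there, and 59.1% and 61.1% with the trend taken out. Bins 1 to 4 before the last bin lay below the far bins (difference -0.30), and the medians went on rising, from -0.046 at 5 bins to 0.043 at 10 and 0.131 at 19, but the number of bins in the last exon was not measured and the positions pool different sets of genes, so a change at the last exon only stays open. RNA integrity values of the samples are not given in the sources used here, so RNA quality stays open as a cause of the shared trend.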
